A study of Mus musculus with 2 samples.

How the data were processed

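Live CD45- cells of 1 Dll1+ and 1 Dll1- mouse mammary tumor were profiled by droplet single-cell RNA sequencing. CD45 is a surface protein of leukocytes, and Dll1 is a membrane ligand of Notch receptors. Per the labels' protocols, both tumors were untreated and were digested with collagenase and hyaluronidase. The cells were stained with antibodies to CD31, CD45 and Ter119, markers of endothelium, leukocytes and erythroid cells, before sorting. Libraries were made with the 10x Single Cell v3 chemistry, per the labels' protocols. How a tumor came to be called Dll1+ or Dll1- is not given in the sources used here.

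The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode. They were made with Cell Ranger 4.0.0, per the file headers, against mm10, per the submitters' processing notes. The annotation release and the Cell Ranger settings are not given in the sources used here. Every deposited barcode had at least 500 UMIs. The files held 32285 gene IDs, and 32158 of them (99.6%) were found in GENCODE M21, from which gene positions on mm10 were taken. Aldoa and Ddit3 each stood under more than 1 gene ID, so they were not counted as measured in the glycolysis and unfolded protein response lists.

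Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs. In the Dll1+ library 11858 of 13819 barcodes passed the UMI and gene minimums and 10581 passed the mitochondrial limit as well. In the Dll1- library 11621 of 13097 and then 11121 passed. Doublet scores came from the scrublet implementation in scanpy. Its automatic threshold marked 7 and 0 barcodes, too few for it to have worked, and the highest-scoring barcodes were removed at a rate of 0.8% per 1000 barcodes, as set in advance. That took out 896 barcodes (8.47%) of the Dll1+ and 989 (8.89%) of the Dll1- library. The cells kept were 9685 and 10132.

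Both libraries were clustered together with scanpy 1.11.5 and leidenalg 0.10.2 in Python 3.11.15. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and a Leiden resolution of 0.6 were used, with no integration of the libraries. Clusters were named only from marker lists fixed before the data were examined. The scoring rule was set after the data were seen. A name needed at least 3 markers, and at least 50% of a list, each detected in at least 20% of the cluster's cells. No other class could have more markers than the named one among the cluster's 10 leading genes. Unnamed clusters of at least 100 cells were split once more at a resolution of 0.5. Epithelial-like and fibroblast-like cells were clustered again at a resolution of 0.4, and a sub-state with at least 2 markers of another class among its 10 leading genes, outnumbering its own, was moved out of the class. A cluster that met the rule for basal cells was led by Krt5 together with genes of skin and hair keratinocytes, and it is called Krt5-led, without a cell type. Other cells left unnamed under these rules made up 3.48% of the Dll1+ and 0.77% of the Dll1- library. A cluster of 10 Dll1+ and 72 Dll1- cells met the rule for epithelial cells and was kept as such. Its 10 leading genes, among them Sprr1a, Krt6a and Krt6b, held no epithelial marker of the lists.

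UMI counts were summed over the cells of a class in each library and given as CPM, the count relative to all UMIs of that class and library. With 1 library per group and no replicates there is no test, p-value or standard error. Every interval is a 95% interval that covers counting error only: exact Poisson for counts and CPM, exact Clopper-Pearson for shares, and exact conditional binomial for ratios. Ratios are log2 of CPM plus 1, Dll1+ over Dll1-. Bounds printed for a ratio are those of the ratio without the added 1, so for genes with few counts in a library they can lie beyond the printed ratio. For a named gene at 0 UMIs in a library the counts are given, with no fold. Shares of cells with a UMI are given as measured and with each cell thinned to 2000 UMIs, leaving out shallower cells. The steps ran with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

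The design, the alternatives, 33 gene lists and the rule for named genes were fixed before the data were examined. A list member was measured with at least 30 UMIs over both libraries in the class. For each list the members at least 1.5-fold higher, at least 1.5-fold lower and between were counted, and the median log2 ratio was set among 10000 random lists of the same size matched on mean expression. That percentile describes these libraries and is not a test. Named genes are, per class, the 12 with the highest and the 12 with the lowest log2 ratio among genes with at least 20 CPM in one library. Mitochondrial and ribosomal protein genes, gene models without a proper symbol, Xist, Tsix and Y-linked genes were left out. So were genes over 5 times higher in another class of the same library than in the class compared. Dll1 and the members of the fixed lists are named beside them. Genes named for Krt5-led, endothelial-like and pericyte-like cells, the genes compared within sub-states, and the genes drawn in the plot of fibroblast-like cells were chosen after their values were seen.

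The alternatives were no removal of doublets, a mitochondrial limit of 10%, a minimum of 3000 UMIs per cell, Leiden resolutions of 1.2 for all cells and 0.8 within a class, and each library clustered alone. For ratios they were TMM factors from edgeR 4.0.16 in R 4.3.3, centring on the median log2 ratio, equal weight for each cell, thinning to 2000 UMIs, a pseudocount of 10 CPM, a minimum of 5 CPM and no filter on list members. Further alternatives weighted alike the sub-states with at least 50 cells of each library, or kept the cells with the lowest share of marker UMIs of other classes. Chosen after the data were seen were leaving out barcodes found in both libraries, a stricter rule for sub-states led by another class's markers, and clustering sub-states without genes at least 1.5-fold apart between the libraries.

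The ratio step was tested on simulated Poisson counts drawn from the real means. In the epithelial-like comparison (5681 genes) 100% of genes changed 2-fold, 4-fold, 0.5-fold or 0.25-fold passed 1.5-fold in the right direction. In the fibroblast-like comparison (5800 genes) the share was 100% at 2-fold, 4-fold and 0.25-fold and 94.0% at 0.5-fold. The 95% intervals held the true ratio for 96.2% and 95.8% of genes. The draws followed the counting model that the intervals assume, so coverage near 95% was built in. Variation between cells or tumors was not simulated.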

Results

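The cells came from 1 Dll1+ and 1 Dll1- mouse mammary tumor, sorted as live CD45- cells. The series concerns Dll1-dependent differences among tumor cells and cancer-associated fibroblasts (CAFs), so the 2 libraries were compared within each of these classes. The Dll1+ library held 117230907 UMIs over 13819 barcodes, with a median of 5853 UMIs per barcode. The Dll1- library held 135960457 UMIs over 13097 barcodes, with a median of 8939. After filtering, 9685 Dll1+ and 10132 Dll1- cells were kept, with medians of 7889 and 9926 UMIs, 2596 and 2721 genes and 5.36% and 3.53% mitochondrial UMIs. There were no replicates, and all intervals cover counting error only.

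Both tumors were mostly made of epithelial-like cells, which express Epcam and the luminal keratins Krt8 and Krt18. These cells were 82.9% (82.1 to 83.6) of the Dll1+ and 85.9% (85.2 to 86.6) of the Dll1- library. Fibroblast-like cells made up a smaller share of the Dll1+ library, 3.48% (3.12 to 3.86) against 5.68% (5.23 to 6.14). Pericyte-like cells, the mural cells of small vessels, made up a larger one, 3.43% (3.07 to 3.81) against 1.72% (1.47 to 1.99). Endothelial-like cells were 3.11% (2.77 to 3.47) and 2.76% (2.45 to 3.10). Their difference of 0.34 percentage points turned to -0.06 with doublets left in and to -0.07 without barcodes of both libraries. Of their clusters, 1 held 260 Dll1+ and 279 Dll1- cells, and another, led by Rgs5, held 41 and 1. A cluster led by Krt5 held 3.43% (3.07 to 3.81) and 3.10% (2.77 to 3.46). It met the rule for basal cells, but Krtdap, Calm4, Tchh and Krt79, known from keratinocytes of skin and hair, were among its 10 leading genes, so it is given no cell type and called Krt5-led. Macrophage-like cells were 18 and 4 in number, and 337 and 78 cells stayed unnamed. The sort removed CD45+ cells, and antibodies to CD31 and Ter119 in the stain can have set the endothelial and erythroid shares. The Dll1+ library was also shallower per cell. The epithelial difference, -3.045 percentage points, turned to 7.05 at a Leiden resolution of 1.2.

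Dll1 was higher in the epithelial-like cells of the Dll1+ tumor and near level in Krt5-led and endothelial-like cells. Dll1 (ENSMUSG00000014773, a protein-coding gene on the minus strand of chromosome 17 from 15367354 to 15376872, mm10) was at 53.6 CPM (52.1 to 55.3; 4382 UMIs) in epithelial-like cells of the Dll1+ library. In those of the Dll1- library it was at 3.99 CPM (3.62 to 4.39; 420 UMIs), a log2 ratio of 3.45. Krt5-led cells had the highest level in both libraries, 90.1 CPM (81.3 to 99.6) and 85.0 CPM (74.8 to 96.2), with overlapping intervals. Endothelial-like cells also had similar levels, 27.5 CPM (19.98 to 36.9) and 24.5 CPM (16.7 to 34.5). Pericyte-like cells held 18 UMIs in the Dll1+ library (6.92 CPM, 4.10 to 10.9) and 2 in the Dll1- library (1.86 CPM, 0.23 to 6.73). Fibroblast-like cells held 8 UMIs (2.53 CPM, 1.09 to 4.98) and 0 UMIs, which allows up to 0.92 CPM.

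At least 1 Dll1 UMI was found in 28.9% (27.9 to 29.9) of the Dll1+ and 3.59% (3.21 to 4.01) of the Dll1- epithelial-like cells, at median depths of 8109 and 10662 UMIs. After thinning to 2000 UMIs, which left out 607 and 197 shallower cells, the shares were 11.0% (10.3 to 11.8) and 0.92% (0.73 to 1.14). Fibroblast-like cells, which hardly express Dll1, gave 2.37% (1.03 to 4.62) and 0% (0 of 575 cells, up to 0.64%) at median depths of 9348 and 6621 UMIs, and 0.62% (0.07 to 2.21) and 0% after thinning. The Dll1- epithelial share after thinning lay above the 0.67% that 0 fibroblast-like cells of its own library allow, but within the interval of those of the Dll1+ library.

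**Figure D1:**
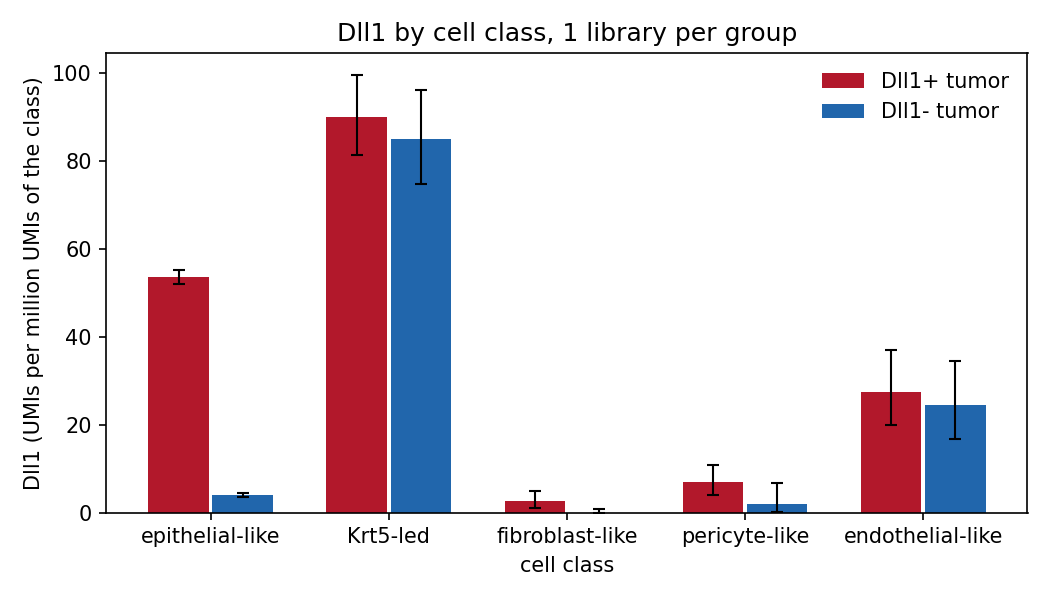
Dll1 in CPM (y axis) by cell class (x axis) in the Dll1+ (red) and Dll1- (blue) library, with exact Poisson 95% intervals as error bars and 1 library per group. The bars differ most in epithelial-like cells, 53.6 against 3.99, and lie close together in Krt5-led cells, 90.1 against 85.0.

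Epithelial-like cells of the Dll1+ tumor also had higher levels of genes that Notch signaling switches on. Of 8 measured Notch target genes 5 were at least 1.5-fold higher, 0 were lower and 3 lay between, with a median log2 ratio of 0.94 (0.85 to 1.03), at the 99.8th percentile of random lists. Hes1, a transcriptional repressor induced by Notch, was at 173 against 58.0 CPM. Hey1 was at 14.6 against 3.35 CPM and Nrarp, a feedback inhibitor of the pathway, at 5.72 against 1.32 CPM, both over 5 times below their endothelial level. Of the 4 receptors, Notch1 (101 against 60.0 CPM) and Notch3 (15.6 against 8.17 CPM) were over 1.5-fold higher, and the list median was 0.53. Among 5 measured Notch ligands 2 were higher, 1 was lower and 2 lay between (median 0.21). Jag1 went the other way from Dll1, at 3.0 against 12.2 CPM, far below its 48.4 and 173 CPM in Krt5-led cells. Weighting alike the 3 sub-states with at least 50 cells of each library gave a Dll1 ratio of 1.40 and a Notch target median of 0.14. These sub-states held 1604 of 8028 Dll1+ and 8606 of 8707 Dll1- cells. The other 6424 Dll1+ cells, with 67.6 CPM of Dll1, were thus left out. The same holds for every epithelial value given below with the shared sub-states weighted alike. Without a filter on low counts the Notch target median was 0.24.

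Chemokine genes were among those with the highest ratios. The interferon-induced Cxcl10 was at 1059 CPM in the Dll1+ and 19.8 CPM in the Dll1- epithelial-like cells (log2 ratio 5.67). Cxcl5, which draws neutrophils, was at 119 against 0.09 CPM, and the monocyte attractant Ccl2 at 462 against 108 CPM. The cytokine Lif was at 256 against 79.6 CPM, while the neutrophil attractant Cxcl1 was lower, at 441 against 952 CPM. Over the 23 cytokines and chemokines 11 were at least 1.5-fold higher, 3 lower and 9 between, with a median of 0.57 (0.47 to 0.62). The NF-kB target list, which shares 4 genes with it, held 7 higher and 3 lower of 16 (median 0.30). The IL-6 and STAT3 list had 1 higher and 2 lower of 10 (median 0.19), with Stat3 at 61.9 against 147 CPM and Pim1 at 82.8 against 221 CPM. The 13 interferon-stimulated genes had a median of 0.33, with 5 higher and 0 lower, among them Ifi27l2a (794 against 177 CPM) and Ifit3 (361 against 152 CPM). MHC class I genes held 3 higher and 1 lower of 9 (median 0.48), with the peptide transporter gene Tap2 at 78.5 against 40.8 CPM and B2m at 2024 against 3678 CPM. With the shared sub-states weighted alike, the interferon and MHC class I medians turned to -1.06 and -0.21. The IL-6 and STAT3 median turned to -0.03 with TMM factors and to -0.155 after thinning.

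Milk protein genes were lower in the Dll1+ tumor. Beta-casein (Csn2) was at 0.95 against 202 CPM, a log2 ratio of -6.70, and alpha-casein (Csn1s1) at 72.9 against 695 CPM. The whey protein genes Lalba and Wap were at 369 against 975 and 32.5 against 133 CPM. Of the 11 milk and alveolar genes 8 were at least 1.5-fold lower, 1 was higher and 2 lay between, with a median of -1.40 (-1.42 to -1.38), at the 0.00 percentile of random lists. The higher member was transferrin (Trf), at 1881 against 742 CPM. Of 12 epithelial genes 5 lay at least 1.5-fold lower, 1 higher and 6 between (median -0.44). The lower ones included Krt7 at 107 against 425 CPM, Cldn4 at 329 against 832 CPM and Krt8 at 2507 against 4426 CPM, and Tjp3 was the higher one at 27.1 against 15.3 CPM. With the shared sub-states weighted alike the milk median was -0.15 and that of the epithelial genes 0.03.

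Progenitor, basal and hormone-sensing genes did not move as blocks. Among 11 mammary stem and progenitor genes 5 were higher, 3 lower and 3 between (median 0.36). The receptor tyrosine kinase gene Kit was at 157 against 36.3 CPM and Sox9 at 238 against 107 CPM, while Cd44 was at 42.2 against 118 CPM. Of 8 basal genes 3 were higher and 1 lower (median 0.39), with Krt14 at 319 against 176 CPM and Krt17 at 73.8 against 133 CPM, both over 5 times below their level in Krt5-led cells. Of 7 hormone-sensing genes 4 were higher and 1 lower (median 0.69, 0.51 to 0.87). They included the transcription factor gene Tbx3 (13.4 against 0.16 CPM), but Foxa1 reached only 3.22 against 1.62 CPM, and Areg, an EGF receptor ligand, was at 15.3 against 61.9 CPM. Wnt target genes split: Axin2 (2.33 against 14.4 CPM) and Znrf3 (6.90 against 18.3 CPM) were lower, and Ccnd1, which encodes cyclin D1, was higher at 466 against 138 CPM. The list held 3 higher and 5 lower of 10 (median -0.49), and the Wnt ligand list 1 higher and 1 lower of 9 (median -0.07).

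Matrix and MHC class II transcripts were also higher in these cells, most of the matrix genes having far higher levels in stromal cells. The thrombospondin gene Thbs1 was at 1227 against 268 CPM and the protease inhibitor gene Timp3 at 331 against 29.6 CPM, neither of them over 5 times higher in another class. The basement membrane collagen gene Col4a1 was at 71.0 against 2.98 CPM, over 5 times below its endothelial level. Matrix glycoproteins held 10 higher and 1 lower of 16 (median 0.98), collagens 11 higher and 0 lower of 17 (0.67) and matrix remodelling genes 5 higher and 1 lower of 17 (0.35). All of the collagens but Col11a1 (51.6 against 16.4 CPM) were over 5 times higher in another class. Of the 6 antigen-presenting CAF genes 4 were higher, the MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 and their chaperone gene Cd74, with Cd74 at 145 against 1.61 CPM and H2-Ab1 at 72.1 against 3.77 CPM, levels over 5 times below those of macrophage-like cells (list median 3.39). With the shared sub-states weighted alike that median was 1.84, and with a pseudocount of 10 CPM it was 1.32 and that of the glycoproteins 0.21. Among the Dll1+ cells Cd74 was at 320 CPM in a sub-state of 4408 cells, of which it was a leading gene. In another, of 1855 cells, it was at 44.8 CPM.

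Cell cycle genes had higher sums in the Dll1+ cells as reported, but not under every alternative. Of 14 S phase genes 11 were at least 1.5-fold higher and 0 lower (median 0.69, 0.64 to 0.77), with the replication helicase genes Mcm5 at 25.0 against 10.2 CPM and Mcm6 at 34.4 against 15.5 CPM. Of 14 G2 and M phase genes 7 were higher and 0 lower (median 0.53), with Top2a at 73.7 against 40.0 CPM. Among the cells with the lowest share of other-class marker UMIs both directions turned, to -0.36 for S phase and -0.82 for G2 and M phase genes, as they did without sub-states with any leading marker of another class, to -0.44 and -1.11. With the shared sub-states weighted alike the G2 and M phase median was -0.44. All 6 cycling markers were at least 1.5-fold above the other sub-states in 2 sub-states, formed in a clustering that used these genes. One held 1.67% (1.40 to 1.97) of the Dll1+ and 6.08% (5.58 to 6.60) of the Dll1- cells. The other held 23.1% (22.2 to 24.0) and 0.09% (0.04 to 0.18). This other one has the fibroblast marker Pdpn among its leading genes and is left out by the rule on any leading marker. The turn under that rule thus came with the loss of 1855 Dll1+ and 8 Dll1- cells with raised cycling markers. Whether the cells with the lowest other-class share lack the same cells was not examined.

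Medians of the remaining lists in epithelial-like cells lay between -0.50 and 0.51. DNA damage repair genes had a median of 0.51, with 3 higher and 0 lower of 15. Mesenchymal transition genes had 5 higher and 0 lower of 10 (0.50), or 1.28 after thinning, with Vim at 33.8 against 10.0 CPM, over 5 times below its pericyte level. Growth factor and receptor genes exchanged with fibroblasts had 4 higher and 3 lower of 12 (0.29, and -0.06 after thinning), with Egfr at 26.4 against 6.53 CPM. Contractile genes had 3 higher and 2 lower of 10 (0.20). TGF-beta targets (3 and 2 of 12, median 0.18), angiogenic factors (3 and 2 of 11, median 0.07) and glycolysis genes (1 and 1 of 12, median 0.05) were at -0.03, -0.14 and -0.20 with TMM factors. Inflammatory CAF genes had 3 higher and 1 lower of 11 (-0.06) and dissociation and immediate early genes 2 and 1 of 13 (-0.09). P53 targets had 2 higher and 4 lower of 12 (-0.27), with the cell cycle inhibitor gene Cdkn1a at 383 against 763 CPM and the apoptosis gene Pmaip1 at 4.74 against 29.0 CPM. Hypoxia genes had 2 higher and 4 lower of 12 (-0.29), with Ndrg1 at 101 against 303 CPM and Car9 at 64.5 against 30.7 CPM. Unfolded protein response genes had 1 higher and 2 lower of 11 (-0.50), with the chaperone gene Hspa5 at 411 against 744 CPM and Xbp1 at 369 against 719 CPM.

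Across all genes, 6247 reached 20 CPM in a library in epithelial-like cells, and 511 were at least 2-fold higher and 171 at least 2-fold lower in the Dll1+ cells. Prpmp5 had 7783 UMIs against 0. The homeobox gene Tlx1 had 5060 UMIs against 3 (log2 ratio 5.93, bounds 9.54 to 13.4) and the peptidase inhibitor gene Pi15 4702 against 2 (5.84, bounds 9.71 to 14.6). Next to Cxcl5 and Cxcl10, the genes with the highest ratios included the potassium channel subunit gene Kcne3 (121 against 0.57 CPM), Ecrg4 (123 against 1.5 CPM), Fetub (55.6 against 0.59 CPM), Tmem213 (56.5 against 0.63 CPM), Gstt2, a glutathione transferase gene (106 against 2.08 CPM), the peptide hormone gene Cck (31.0 against 0.04 CPM) and Mia (220 against 6.53 CPM). Those with the lowest, beside the caseins Csn2 and Csn1s1, were the cohesin gene Rec8 (0.42 against 32.2 CPM), the chromatin protein gene Hmga2 (2.13 against 22.4 CPM), Bpifb5 (11.4 against 73.7 CPM), Prtn3 (38.7 against 222 CPM), the membrane mucin gene Muc4 (18.1 against 105 CPM) and Lgals7, which encodes galectin-7 (333 against 1809 CPM). Nfil3, Ckb, Pmaip1 and Mtus2 completed them, with log2 ratios from -2.43 to -2.37. The median log2 ratio over genes was 0.17, and TMM factors shifted ratios by -0.26 before the added 1. Of the genes at least 2-fold apart 74.9% were higher as reported, 52.5% (336 higher, 304 lower) with TMM factors and 61.3% after centring, and weighting the shared sub-states alike gave 99 higher and 36 lower.

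The tumor cells of the libraries lay largely in different clusters. Of the 8028 Dll1+ epithelial-like cells 4408 and 1855 fell in 2 sub-states that held 3 and 8 Dll1- cells, so these sub-states may be the library rather than a kind of cell. Most Dll1- cells (4960 and 3117 of 8707) fell in 2 others. Where sub-states were shared, the 1604 Dll1+ cells had 13.8 CPM of Dll1 (12.2 to 15.4) and the 8606 Dll1- cells 3.97 CPM (3.60 to 4.37). By sub-state the levels were 16.1 (14.2 to 18.2) against 4.68 (4.16 to 5.25) CPM, 12.3 (8.40 to 17.3) against 3.07 (2.48 to 3.76) CPM and, in the one led by cell cycle genes, 3.51 (1.75 to 6.28) against 2.49 (1.67 to 3.58) CPM with overlapping intervals. The other 6424 Dll1+ cells had 67.6 CPM (65.6 to 69.7). A Dll1 UMI was found in 12.5% (10.9 to 14.2) of the Dll1+ and 3.59% (3.21 to 4.01) of the Dll1- cells of shared sub-states, and in 3.41% and 0.91% of the 1552 and 8417 cells with 2000 UMIs after thinning. Clustered without the genes at least 1.5-fold apart, a choice made after seeing the data, the cells formed 6 sub-states. In those with 45.2% and 19.4% of the Dll1+ cells and 1.08% and 1.24% of the Dll1- cells, Dll1 was at 76.0 (72.9 to 79.2) against 4.51 (0.93 to 13.2) CPM and 119.9 (113 to 127) against 4.73 (0.57 to 17.1) CPM, the Dll1- levels from 3 and 2 UMIs. In those with 6.28% and 18.4% of the Dll1+ and 33.2% and 57.4% of the Dll1- cells, it was at 14.2 (11.0 to 17.9) against 2.88 (2.28 to 3.58) CPM and 21.7 (19.7 to 23.97) against 4.73 (4.21 to 5.29) CPM. In the one with 10.6% of the Dll1+ and 6.21% of the Dll1- cells it was at 21.1 (19.0 to 23.35) against 2.43 (1.63 to 3.49) CPM. The smallest, with 10 Dll1+ and 81 Dll1- cells, held 0 and 3 UMIs. In that clustering 99.9% of the Dll1+ cells lay in sub-states with at least 50 cells of each library. Leaving out the genes that differ draws the libraries together by construction. The sub-states of 3627 and 1559 Dll1+ cells counted among them with 94 and 108 Dll1- cells.

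Fibroblast-like cells of the Dll1+ tumor had higher levels of structural matrix genes. Col1a1, the major fibrillar collagen gene, was at 11644 against 4944 CPM (log2 ratio 1.24, 1.21 to 1.26), Col8a1 at 906 against 215 CPM and Col12a1 at 508 against 208 CPM. Of 17 collagens 9 were at least 1.5-fold higher, 0 lower and 8 between (median 0.61, 0.56 to 0.67). Of 17 matrix glycoproteins 9 were higher and 0 lower (median 0.78, 0.74 to 0.80), among them periostin (Postn, 2088 against 976 CPM), biglycan (Bgn, 4993 against 2044 CPM) and tenascin C (Tnc, 127 against 35.0 CPM). Both lists lay at the 100th percentile of random lists. Matrix remodelling genes had 7 higher and 1 lower of 17 (0.50), with the crosslinking enzyme gene Lox at 892 against 417 CPM and the urokinase gene Plau at 12.3 against 50.2 CPM. Of 12 TGF-beta targets 6 were higher and 0 lower (0.56), with Ccn2 at 537 against 236 CPM, Pmepa1 at 1082 against 473 CPM and Ltbp2 at 170 against 40.3 CPM. Without the sub-state with the highest Tagln, 1 TGF-beta target was higher of 10 measured (median 0.18). The medians were then 0.51 for collagens, 0.43 for glycoproteins and 0.24 for matrix remodelling genes.

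Contractile genes, which mark myofibroblasts, were higher too. All 6 measured members were at least 1.5-fold higher (median 1.08, 0.91 to 1.16), with smooth muscle actin (Acta2) at 257 against 119 CPM (log2 ratio 1.11, 0.95 to 1.28) and Tagln at 393 against 187 CPM. Acta2, Tagln, Myl9 and Actg2 were over 5 times higher in pericyte-like cells, and Tpm2 in Krt5-led cells. Among cells with the lowest share of other-class marker UMIs (205 Dll1+ and 251 Dll1- cells) the contractile median was 0.39. In the single fibroblast sub-state with at least 50 cells of each library it was 0.30, and the medians of glycoproteins and collagens were both 0.12 and that of the TGF-beta targets -0.02. That sub-state held 100 Dll1+ and 116 Dll1- cells, and Col1a1 in it was at 11258 against 5937 CPM.

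Inflammatory CAF genes were near level, with 1 higher, 1 lower and 9 between of 11 (median -0.16, and 0.26 in the shared sub-state). Il6 was at 161 (148 to 176) against 179 (167 to 193) CPM, while the chemokine gene Cxcl12 was at 1521 against 924 CPM. Clec3b, at 1132 against 1870 CPM, was the member that lay lower. The wider list of cytokines and chemokines had 8 higher and 2 lower of 19 (0.49), with Cxcl14 at 1281 against 453 CPM and Il33 at 589 against 305 CPM. NF-kB targets had 0 higher and 0 lower of 15 (-0.06), and the IL-6 and STAT3 list 1 and 2 of 10 (-0.15). Interferon-stimulated genes had 0 higher and 6 lower of 13 (-0.52, -0.67 to -0.36), among them Isg15 (134 against 245 CPM) and Ifi27l2a (465 against 1063 CPM). MHC class I genes had 0 higher and 0 lower of 8 (0.07). In the shared sub-state the NF-kB, IL-6 and STAT3 and MHC class I medians had the other sign (0.17, 0.14 and -0.16). Of 3 measured antigen-presenting CAF genes 2 were higher, with the acute phase gene Saa3 at 711 against 106 CPM and Cd74 at 8.54 against 1.24 CPM (list median 2.09). That median is the ratio of Cd74, the middle of the 3 genes. Cd74 had 15 UMIs in 125 Dll1+ and 2 UMIs in 45 Dll1- cells of the fibroblast sub-state with the highest Tagln. In epithelial-like cells Cd74 was at 320 CPM in 4408 Dll1+ and 1.58 CPM in 4960 Dll1- cells, the largest sub-state of each library. Whether RNA of those cells gave the fibroblast-like Cd74 counts was not tested. With a pseudocount of 10 CPM the list median was 0.72, without the filter on low counts 0.84 and in the shared sub-state 1.42.

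Notch and Wnt genes showed no common direction in fibroblast-like cells. Of 5 Notch targets only Heyl was at least 1.5-fold higher, at 16.1 against 3.73 CPM (51 and 15 UMIs), over 5 times below its pericyte level. Hes1 was at 102 (91.0 to 114) against 76.8 (68.5 to 85.8) CPM, and the list median of 0.36 turned to -0.30 in the shared sub-state. Notch2 was at 52.5 against 85.0 CPM (1 lower and 2 between of 3 receptors, median 0.36 and in the shared sub-state -0.07), and the 1 measured ligand, Jag1, at 52.8 against 57.4 CPM (-0.12). Among 6 Wnt ligands 2 were higher and 1 lower (0.22, and -0.24 in the shared sub-state), with Wnt2 at 46.2 (39.0 to 54.3) against 84.2 (75.5 to 93.7) CPM and Wnt9a at 39.5 against 17.1 CPM. Wnt targets had 0 higher and 1 lower of 4 (-0.28). Growth factors and receptors had 5 higher and 2 lower of 10 (0.49), with Igf1 at 335 against 208 CPM, Fgf7 at 111 against 61.4 CPM and Fgf2 at 61.7 against 122 CPM. Angiogenic factors had 3 higher and 2 lower of 10 (0.38), with Angpt1 at 27.2 against 11.7 CPM and Vegfa at 49.7 against 90.4 CPM.

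The other lists in fibroblast-like cells were mostly between. G2 and M phase genes had 4 higher and 0 lower of 12 (0.38), p53 targets 2 and 0 of 12 (0.18), hypoxia genes 2 and 1 of 9 (0.10), glycolysis genes 0 and 1 of 12 (0.23), mesenchymal transition genes 1 and 0 of 11 (0.02) and DNA damage repair genes 0 and 0 of 11 (0.01). S phase genes had 0 higher and 3 lower of 11 (-0.36), unfolded protein response genes 0 and 3 of 10 (-0.38), dissociation genes 0 and 1 of 13 (-0.27), stem and progenitor genes 0 and 1 of 7 (-0.19) and hormone-sensing genes 0 and 1 of 3 (-0.57). Epithelial genes had 0 higher and 4 lower of 9 (-0.58), for example Krt8 at 71.8 against 105 CPM, and milk genes 2 higher and 3 lower of 7 (-0.24), with Csn3 at 55.0 against 158 CPM, all over 5 times below their epithelial level. Basal genes had 1 higher and 1 lower of 4 (0.26), and 1.44 with doublets left in. In the shared sub-state the medians of G2 and M phase genes (-0.12), p53 targets (-0.20), angiogenic factors (-0.06), stem and progenitor genes (0.15), DNA damage repair genes (-0.40) and hypoxia genes (-0.003) had the other sign, as did that of milk genes with doublets left in (0.06) and after thinning (0.26).

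**Figure D2:**
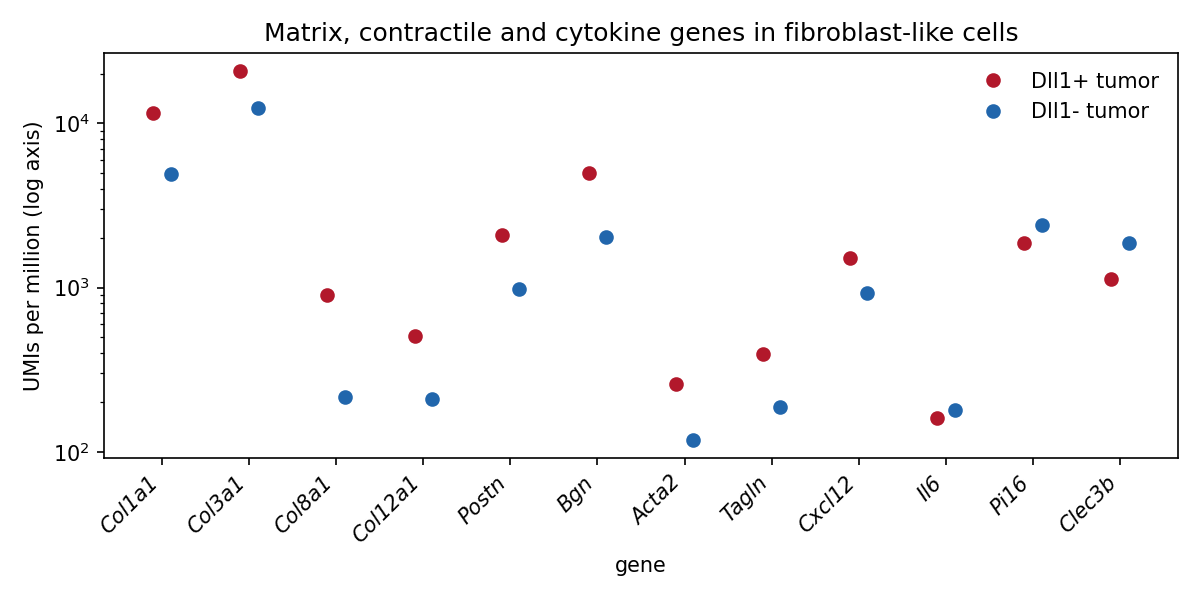
CPM (y axis, log scale) of matrix, contractile and cytokine genes (x axis) in fibroblast-like cells of the Dll1+ (red) and Dll1- (blue) library, 1 point per library, with genes chosen after their values were seen. Col1a1 lies at 11644 against 4944 and Acta2 at 257 against 119, while Il6 lies at 161 against 179.

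Across all genes, 6140 reached 20 CPM in a library in fibroblast-like cells, and 172 were at least 2-fold higher and 63 at least 2-fold lower in the Dll1+ cells. The highest ratios belonged to Gfra1, a co-receptor gene for GDNF (40.2 against 2.24 CPM), the hyaluronan-degrading factor gene Cemip (171 against 13.9 CPM), Megf6, Cpxm2, Cxcl5 (66.1 against 6.71 CPM), the retinoic acid hydroxylase gene Cyp26b1 (38.6 against 3.73 CPM), Smoc2 (244 against 29.1 CPM), Thbs4, Ccbe1, Saa3, fibromodulin (Fmod, 108 against 15.4 CPM) and the calcification inhibitor gene Mgp (3105 against 479 CPM). The lowest belonged to Bmp2 (3 against 85 UMIs, log2 ratio -3.50, bounds -6.78 to -2.88), the lipoprotein receptor gene Vldlr (6.32 against 45.5 CPM), Smpd3, the transcription factor genes Irf4 and Zbtb16, Car8, Calml4, Procr, which encodes the protein C receptor (26.2 against 104 CPM), Plau, the endothelin gene Edn1 (18.7 against 67.8 CPM), Uchl1 and the thrombomodulin gene Thbd (79.4 against 270 CPM). In the shared sub-state Megf6 (-0.083), Cpxm2 (-0.39), Smpd3 (0.016) and Car8 (0.35) turned direction. Thinning to 2000 UMIs gave 327 genes higher and 165 lower.

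Fibroblast-like cells fell into sub-states that the libraries filled differently. The myofibroblast-like sub-state, with 9 of 10 myofibroblastic markers at least 1.5-fold above the other sub-states, held the most Dll1+ cells (125 of 337), and the sub-state with the highest Pi16 the most Dll1- cells (354 of 575). Pi16 marks fibroblasts of the adventitia and connective tissue. Clustered without the genes at least 1.5-fold apart, a Tagln-high sub-state (901 and 894 CPM of Tagln in the Dll1+ and Dll1- library) held 39.5% of the Dll1+ and 16.2% of the Dll1- cells. The Pi16-high sub-state (3102 and 3518 CPM of Pi16) held 29.7% and 62.1%, and the remaining one, with the highest Il6 (272 and 249 CPM), 30.9% and 21.7%. Within the myofibroblast-like sub-state of the clustering on all variable genes the order was the opposite of that in the class. Tagln is a leading gene of that sub-state, so its cells can have been picked in part by their Tagln. Tagln was at 978 (923 to 1037) CPM in 125 Dll1+ cells and 2063 (1912 to 2224) CPM in 45 Dll1- cells, and Acta2 at 544 (502 to 587) and 1084 (975 to 1202) CPM. Il6 lay higher in some sub-states and lower in others, with intervals that overlapped in all but the one led by Apoe and Cxcl13. It was at 337 (302 to 375) and 259 (227 to 294) CPM in the sub-state of 100 Dll1+ and 116 Dll1- cells led by Apoe and Cxcl13, at 137 (95.8 to 189) and 187 (169 to 206) CPM in the one with the highest Pi16, and at 76.9 (61.9 to 94.5) and 102 (70.9 to 143) CPM in the myofibroblast-like one. In the 2 others it was at 60.8 (42.1 to 85.0) and 45.4 (26.5 to 72.7) CPM, and at 40.2 (14.8 to 87.5) and 109 (67.5 to 167) CPM. Col1a1 was higher in the Dll1+ cells of every sub-state. Its level was 12743 against 7072 CPM in the myofibroblast-like one and 5052 against 3651 CPM in the one with the highest Pi16. The one led by Apoe and Cxcl13 had 11258 against 5937 CPM, and the 2 others 13002 against 6975 and 12196 against 7506 CPM. Col11a1 in the myofibroblast-like one was at 226 (199 to 255) against 274 (221 to 337) CPM.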

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

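The tests on barcodes shared by the libraries, on cycling cells and on surrounding tissue were chosen only after the result was seen, as were the clustering without genes that differ and the counting interval used to read the test on the mix of fibroblast sub-states.

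In the sub-states that both libraries shared, Dll1+ tumor cells had 13.8 CPM of Dll1 (12.2 to 15.4), between the 3.97 CPM (3.60 to 4.37) of the Dll1- cells and the 67.6 CPM (65.6 to 69.7) of the other Dll1+ cells. Carry-over of barcodes from the Dll1- library is argued against, since 0.37% (0.14 to 0.81; 6 of 1604) of these cells had a barcode also deposited for that library. By the rule set in advance, free RNA of the other Dll1+ tumor cells is argued against as the source of all their Dll1 counts. Dll1 stood at 20.3% (18.1 to 22.8) of its level in those cells. The lower bound was 4.13 times the median of the 12 genes with the highest ratios (4.4%, from 3.4 to 22.4), although Kcne3 (22.4%) and Cxcl5 (19.9%) stood as high. These genes were picked from the same cells, and Prpmp5, Kcne3, Cxcl10 and Tmem213 among them lead an unshared sub-state. The clustering can thus have lowered their share, which limits this test. Cycling cells of the Dll1-high kind are argued against, since Dll1 in the cycling one of these sub-states was at 3.51 CPM (1.75 to 6.28), near the 2.49 CPM (1.67 to 3.58) of its Dll1- cells and below the 16.1 CPM (14.2 to 18.2) and 12.3 CPM (8.40 to 17.3) of the other shared sub-states, while in an unshared sub-state that also had raised cycling markers it was at 56.1 CPM (53.3 to 58.9). A candidate explanation that stays open is a tumor cell state with an intermediate level of Dll1 outside the cycling sub-state. Counts summed over cells cannot tell such a state from a mix of cells with high and low Dll1. Beyond the share of cells with a UMI, levels per cell were not examined. The pattern was found and tested on the same cells, and the levels per sub-state depend on the clustering. Clustered without the genes that differ, a sub-state with 10.6% of the Dll1+ and 6.21% of the Dll1- cells had 21.1 against 2.43 CPM. Whether that sub-state holds the cycling cells was not examined.

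The share of fibroblast-like cells in the sub-state with the highest Pi16 differed by -50.6 percentage points, Dll1+ minus Dll1-, and by -32.4 points when clustered without the genes that differ. Depth is argued against as the whole cause, since the difference was -39.6 points at or above the median of 7520 UMIs (8.0% against 47.6%) and -54.0 points below it (17.0% against 70.9%). Epithelial RNA is argued against too, since among the cells with the lowest share of epithelial marker UMIs the difference was -46.9 points (11.2% of 205 cells against 58.2% of 251 cells). How much tissue around each tumor was taken cannot be told apart from the group with 1 tumor in each; the share of the Krt5-led cluster, given as a description, differed by 0.33 points. The Dll1 status of the tumor stays among the open explanations, untested.

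Contractile genes had a median log2 ratio of 1.08 in fibroblast-like cells. RNA of pericyte-like cells is argued against as the source: the 5 pericyte markers differed by a median of 0.04% of their pericyte level and the contractile genes by 4.86%, with Rgs5 at 3.5 and 1.5 CPM in fibroblast-like and 4633 CPM in pericyte-like cells. Without the sub-state with the highest Tagln the contractile median over the same 6 genes was 0.58 (0.43 to 0.97), and over the 5 genes that still had 30 UMIs it was 0.60. The test set in advance asked only whether the median fell under 0.585, the log2 of 1.5-fold, which 0.58 does and 0.60 does not. With the interval on both sides of it, this test cannot tell a different mix of sub-states from a difference within them. The sub-state left out held 37.1% of the Dll1+ and 7.83% of the Dll1- cells. Within it Tagln (978 against 2063 CPM) and Acta2 (544 against 1084 CPM) were lower in the Dll1+ cells. Clustered without differing genes, the Tagln-high sub-state had level Tagln (901 against 894 CPM). Tagln is a leading gene of the sub-state left out, so its cells can have been picked in part by their Tagln. The order within it therefore cannot decide whether Tagln or Acta2 rose there. The clustering without differing genes, which did not use Tagln, showed no difference in Tagln within its sub-state. Acta2 was not compared in it. Across the remaining sub-states both genes went both ways. The Dll1 status of the tumor stays open and untested.

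Hormone-sensing genes had a median of 0.69 over 7 genes in epithelial-like and -0.57 over 3 genes in fibroblast-like cells. These are opposite signs whose difference was not tested. Of the 3 genes 1 was at least 1.5-fold lower and 2 lay between. S phase genes had a median of 0.69 in epithelial-like and -0.36 in fibroblast-like cells, again with a difference that was not tested. The epithelial S phase median turned to -0.36 among cells with the lowest share of other-class marker UMIs and to -0.44 under the stricter marker rule, the sign of the fibroblast-like cells. The stricter rule left out the sub-state of 1855 Dll1+ and 8 Dll1- cells, in which all 6 cycling markers were raised.

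Among the data outside the comparisons, 109 barcodes were deposited for both libraries. A group of 12 cells in the Dll1+ and 12 in the Dll1- library stayed unnamed and was led by genes of glial cells, with 16 and 9 UMIs of Olig1 and 26 and 24 of Fabp7. All of these cells had a barcode found in both libraries, and their median depths were 1113 and 1090 UMIs.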

How the results depend on the processing

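No paired analysis was possible because each group had 1 library and no test was run. Leaving out barcodes of both libraries, leaving out sub-states with any leading marker of another class and clustering without genes that differ were chosen after seeing the data. The epithelial share difference (-3.045 percentage points) was -1.10 with doublets left in, -1.94 at 3000 UMIs, -1.36 without barcodes of both libraries and -22.1 under the stricter marker rule, and it reversed to 7.05 at a Leiden resolution of 1.2. The fibroblast share difference kept its direction under every alternative run. Epithelial genes at least 2-fold higher and lower (511 and 171) were 336 and 304 with TMM factors, 337 and 113 with a pseudocount of 10 CPM, 99 and 36 with sub-states weighted alike, 1003 and 298 at 5 CPM, and 110 lower under the stricter marker rule. The Dll1 ratio was 3.22 with TMM factors, 3.29 centred, 3.68 with equal cell weights, 2.19 with a pseudocount of 10 CPM and 1.40 with sub-states weighted alike. Epithelial lists at least 1.5-fold apart (7) were 12 after thinning, 2 with a pseudocount of 10 CPM, 3 with sub-states weighted alike and 13 in cells with the lowest share of other-class marker UMIs, where S phase genes reversed to -0.36, as they did to -0.44 under the stricter marker rule. Fibroblast genes higher and lower (172 and 63) were 327 and 165 after thinning, 114 and 30 with a pseudocount of 10 CPM, 384 and 158 at 5 CPM, and 101 lower with sub-states weighted alike. That alternative gave 2 fibroblast lists 1.5-fold apart where 4 were reported. These were the antigen-presenting list of those 4 (1.42) and the basal list (0.79). It also reversed Megf6 (-0.083), Cpxm2 (-0.39), Smpd3 (0.016) and Car8 (0.35). By construction this alternative rests on 3 epithelial sub-states and 1 fibroblast sub-state. The 3 epithelial ones held 1604 of 8028 Dll1+ and 8606 of 8707 Dll1- cells. The Pi16-high share difference (-50.6) was -44.2 with doublets left in, -45.0 at 10% mitochondrial UMIs, -33.4 at a resolution of 0.8 and -32.4 clustered without differing genes. The share of Dll1+ tumor cells in shared sub-states (19.98%) was 23.0% at 3000 UMIs, 21.8% at a resolution of 0.8, 21.4% without barcodes of both libraries, 26.0% under the stricter marker rule and 99.9% clustered without differing genes. A higher minimum of CPM tests fewer genes and a pseudocount shrinks ratios by construction. Leaving out differing genes draws the libraries together by construction. Sub-states of 3627 Dll1+ and 94 Dll1- cells and of 1559 and 108 then counted as shared. The stricter marker rule left out the epithelial sub-state of 1855 Dll1+ and 8 Dll1- cells with raised cycling markers. Elsewhere the cause was not tested. Over all alternatives, 523 of 837 list medians, 396 of 576 named gene ratios and 24 of 28 other shares stayed within counting error of the reported value, 312, 176 and 4 moved, and 2 list medians and 4 named genes reversed. A median counts as reversed only if it was reported at least 1.5-fold apart. Of the 837 list medians 59 had the other sign, as had 2 of the 28 other shares. Depth limits the fibroblast-like comparison, where 8 and 0 Dll1 UMIs and lists with 1 to 5 measured members carry wide intervals.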

Other observations

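No test was run for this part, and the genes named in it were chosen after their values were seen.

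Endothelial-like cells of the Dll1+ tumor had higher levels of antigen-presenting CAF genes. In the cluster that both libraries filled (260 and 279 cells) the invariant chain gene Cd74 was at 173 against 6.1 CPM, the MHC class II gene H2-Ab1 at 59.3 against 6.9 CPM and the T cell attractant Cxcl9 at 592 against 69.7 CPM. Ubd was at 92.7 against 4.6 CPM, Iigp1 at 299 against 68.9 CPM and the vessel-destabilizing factor Angpt2 at 261 against 56.6 CPM. Of 5 antigen-presenting CAF genes 4 were at least 1.5-fold higher and 0 lower (median 2.93), while interferon-stimulated genes had 4 higher, 0 lower and 9 between of 13 (0.14). Of 7 epithelial genes 4 were higher and 1 lower there (0.68), and the pericyte gene Rgs5 was at 30.7 against 3.1 CPM. P-selectin (Selp) was lower at 101 against 296 CPM, as was E-selectin (Sele) at 34.8 against 94.2 CPM, and so were Cxcl1 (227 against 1137 CPM) and the granulocyte factor Csf3 (37.5 against 123 CPM). An entry of Ccl21a (85.9 against 712 CPM), Mmrn1 (7.5 against 55.9 CPM) and Reln (2 against 29 UMIs) were lower too. Whether the libraries differ in the mix of cells within this cluster was not tested. Pericyte-like cells in the cluster of 316 and 174 cells had higher Cxcl9 (365 against 55.9 CPM) and Iigp1 (430 against 164 CPM) and lower Cxcl1 (968 against 1996 CPM), but interferon-stimulated genes there had 1 higher and 3 lower of 13 (-0.30), with Ifi27l2a at 94.2 against 135.9 CPM. TGF-beta targets there had 1 higher and 6 lower of 12 (median -0.60), unlike the 6 higher and 0 lower in fibroblast-like cells, a difference that was not tested. Genes of other cell types moved in the same pericyte cluster: epithelial genes had 0 higher and 6 lower of 7 (-1.20), milk genes 0 and 5 of 7 (-1.59) and basal genes 3 and 0 of 5 (0.83).

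Cells of the Krt5-led cluster, 332 and 314 in number, had similar Dll1 in both libraries and differed in other genes. The mix of cells within this cluster was not compared between the libraries. Of 9 contractile genes 8 were at least 1.5-fold higher and 0 lower in the Dll1+ cells (median 2.18), and of 13 collagens 10 were higher and 1 lower (1.51). All of these collagens but Col11a1 and Col18a1, and Actg2 of the contractile genes, were over 5 times higher in another class. Antigen-presenting CAF genes had 4 higher and 1 lower of 5 (1.93) and epithelial genes 0 higher and 5 lower of 11 (-0.53). G2 and M phase genes had 11 higher and 0 lower of 14 (1.14) and Wnt targets 6 higher and 2 lower of 11 (0.80), while interferon-stimulated genes had 2 higher and 8 lower of 13 (-0.63). Krt6b was lower at 3.98 against 117 CPM, as were Krt1 at 31.8 against 243 CPM and trichohyalin (Tchh) at 287 against 2024 CPM. The transcription factor gene Tfap2b had 219 against 0 UMIs. Notch receptors had 0 higher and 3 lower of 3 (-1.05) and Notch targets 2 higher and 2 lower of 6 (-0.43).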
